A study of Drosophila melanogaster with 3 samples.

How the data were processed

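The samples were 3 biological replicates of chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster prepupae, both sexes pooled, with a labelled age of 24 hours. The flies carried a transgene that expresses the RB isoform of Spineless (ss) with green fluorescent protein (GFP) at its C terminus, and the immunoprecipitation was directed at GFP. Per the labels, chromatin was sheared by sonication. All 3 replicates belong to one group, named by the labels as replicates 1, 2 and 3 of the same line and stage.

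Each replicate came with a relaxed list of 30000 regions on each of the genome builds dm6 and dm3, and the deposited files also hold a relaxed list of 30000 regions from the pooled replicates on each build. Per the text files deposited with the samples, the relaxed lists were called on alignments together with a control alignment, and the replicate and pooled lists were then passed to the irreproducible discovery rate (IDR) procedure, which keeps regions that rank alike across replicates. The peak caller, the aligner and their versions are not given in the sources used here. The resulting list of reproducible regions is called the IDR list below. The authors' signal value of each region, a score that is never negative, was used only to rank regions within a list. The deposited lists also give a q-value per region as −log10 q, which was read but not used to rank regions. No list gives read counts, so the sequencing depth of each replicate is unknown, and no precision that depends on depth can be stated. The control alignment was not used here.

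Every region of the dm6 IDR list was found with the same coordinates and signal in the pooled dm6 list, where 8942 regions reach the lowest signal of the IDR list. The IDR list therefore holds the 8942 pooled regions with the highest signal. The same held on dm3 for 8897 regions. Coordinates are on dm6, counted from 1. No region end in the dm6 lists lay past the end of its arm in the reference sequence. Genes came from Ensembl release 115 on the same assembly, and 13945 protein-coding genes on X, 2L, 2R, 3L, 3R and 4 were used. The dm3 lists were used only for counts, overlaps and correlations, and no coordinate was converted.

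The highest 8942 regions of each replicate list by signal form its top list, and the lowest 8942 its background list. An IDR region counted as found in a replicate when a region of that list had its summit within 100 bp. The share found was given with an exact Clopper-Pearson 95% interval, which covers counting error only. Spearman's rho of signal was computed across IDR regions for each pair of replicates, with no p-value because regions are not replicates. A summit within 500 bp of an annotated start of a protein-coding gene was called promoter. Other summits were assigned in the order 5' UTR, coding sequence, 3' UTR, other parts of a gene (mostly introns) and outside genes. The promoter share was compared, one-sided, with 1000 sets of uniform positions on the same arms, for which the smallest possible p is 0.001. Top and background lists were compared by an exact sign permutation over 3 replicates, for which the smallest two-sided p is 0.25. The other location classes were described against 100 sets of uniform positions without a test.

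Before the data were examined, 28 gene lists were fixed. They cover functions known for Spineless, signalling pathways, tissue markers that a whole animal could contribute, and large gene families for comparison. Of 1005 list places, 994 matched a protein-coding gene of the annotation. For each list the number of genes with an IDR summit within 500 bp of a start was compared, two-sided, with 10000 random lists matched on the number of starts and on quartile of gene length. This is a permutation test within strata, and its smallest p is 0.0002. Values were adjusted by Benjamini-Hochberg over the 28 lists at a threshold of 0.05. Genes are not independent replicates, and neighbours can share a summit. Words on either strand were counted within 50 bp of the summit and in a window of the same 101 bp centred 350 bp to the right. The shares were compared by a two-sided exact McNemar test, adjusted over 12 words. This test takes regions as units, which are not replicates, and some summits lie within 200 bp of each other. Its p-values therefore do not measure spread between replicates. GC content was measured in windows of 101 bp.

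Named genes followed a rule fixed with the lists. It names ss and its partner tgo, the gene with the nearest start for each of the 20 highest IDR summits, and members of lists. For lists past the threshold, and always for the appendage, retinal, sensory organ, ecdysone and bHLH-PAS lists, it takes up to 4 members with the highest signal within 500 bp of a start and up to 2 members with no promoter summit in list order. Signal values given for list members are those of promoter summits, and summits farther from a start, which can be stronger, were not ranked.

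Summit matching, the promoter share, the gene list test and the word test were tested on simulated data. With 8942 simulated regions, a planted overlap of 60.27% was recovered as 60.56% and an expected promoter share of 38.19% as 38.06%. The planted summits were moved by less than the matching distance, so this checks the counting and not the choice of distance. Of 200 simulated lists of 40 genes drawn from the 13945 genes without any effect, 5% had p under 0.05. Hits were drawn independently for each gene, so summits shared by neighbours were not simulated. At the same unadjusted threshold and list size, the list test recovered 77.5% of lists at 3-fold odds and 99.5% at 6-fold odds. Recovery after the adjustment used for the fixed lists was not simulated. Nor was recovery for smaller lists, such as the bHLH-PAS list with 11 genes. A fixed list that did not pass is therefore not shown to be without an effect. Alternatives changed the matching distance, list size, build, promoter distance, gene set, background, flank and statistic, used only the 4471 strongest IDR regions, or left out each replicate in turn. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.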

Results

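Binding of Spineless was mapped by ChIP-seq in whole Drosophila prepupae. Spineless is a bHLH-PAS transcription factor, the fly relative of the aryl hydrocarbon receptor, and is known for its roles in antenna and leg identity, bristles and photoreceptor subtypes. The protein carried a GFP tag and was recovered with an antibody against GFP. The data comprise 3 biological replicates of one line at one stage, so no groups were contrasted. The questions were how far the replicates recovered the same regions, where those regions lie, which genes carry them, which sequence words they hold and what is bound at ss itself. Values of region signal are the authors' own scores and serve to rank regions within a list. Sequencing depth was unknown.

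The IDR list held 8942 regions on dm6, with a median width of 460 bp. They were spread over all large arms, from 62.2 regions per Mb on 3R to 75.9 per Mb on X. The small 4th chromosome held 25 regions, or 18.5 per Mb. In the replicates' top lists the density was 76.2 ± 3.92 per Mb on X and 23.2 ± 3.43 on chromosome 4 (SD, n = 3). The background lists had 74.99 ± 6.99 per Mb on X and 16.3 ± 2.67 on chromosome 4 (SD, n = 3), so the lower density on 4 was also present among the weakest calls.

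The strongest regions were shared by all replicates. The share of IDR regions found in a replicate's top list was 81.1% ± 2.36 (SD, n = 3), and 5315 of 8942 regions, or 59.4% (95% interval 58.4 to 60.5), were found in the top lists of all 3. Moving the summits by 10 kb gave 1.52%. Among the highest-ranked 1789 regions 96.0% were in all 3 top lists (94.96 to 96.8), against 4.47% (3.56 to 5.53) of the lowest-ranked 1789. Only 1.29% of the regions were in no top list. Because the IDR list is a signal threshold on the pooled data, it is not independent of the replicates. Signal ranks across regions gave a Spearman's rho of 0.723 for replicates 1 and 2, 0.801 for 1 and 3 and 0.767 for 2 and 3, computed over 7973, 8124 and 8085 regions that are not independent of each other. The share in all 3 top lists depended on the list size, at 33.0% with top lists of 4471 regions, and on the matching distance, at 44.5% within 50 bp and 71.9% by overlap of 1 bp.

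Summits lay mostly at promoters and in introns and rarely in coding sequence. Of the IDR summits, 3137 or 35.1% were within 500 bp of a protein-coding start, 3.07 times the 11.4% of uniform positions (one-sided permutation p = 0.001, the smallest that 1000 sets can give). A further 43.0% were in introns or other parts of genes, compared with 39.3% of uniform positions, and 19.5% were outside genes, compared with 30.0%. Coding sequence held 48 summits, 0.537%, compared with 13.9% of uniform positions. In the replicates' top lists the promoter share was 36.1% ± 2.52, and in their background lists 12.8% ± 0.974 (SD, n = 3). The difference of 23.3 ± 1.54 percentage points was positive in all 3 replicates (exact two-sided sign permutation p = 0.25, the smallest that 3 replicates allow). Promoter summits lay at a median of 56 bp upstream of the start, and 62.0% of them were upstream. Each replicate's top list showed the excess, with 39.0% in replicate 1, 34.3% in replicate 2 and 34.9% in replicate 3.

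**Figure D1:**
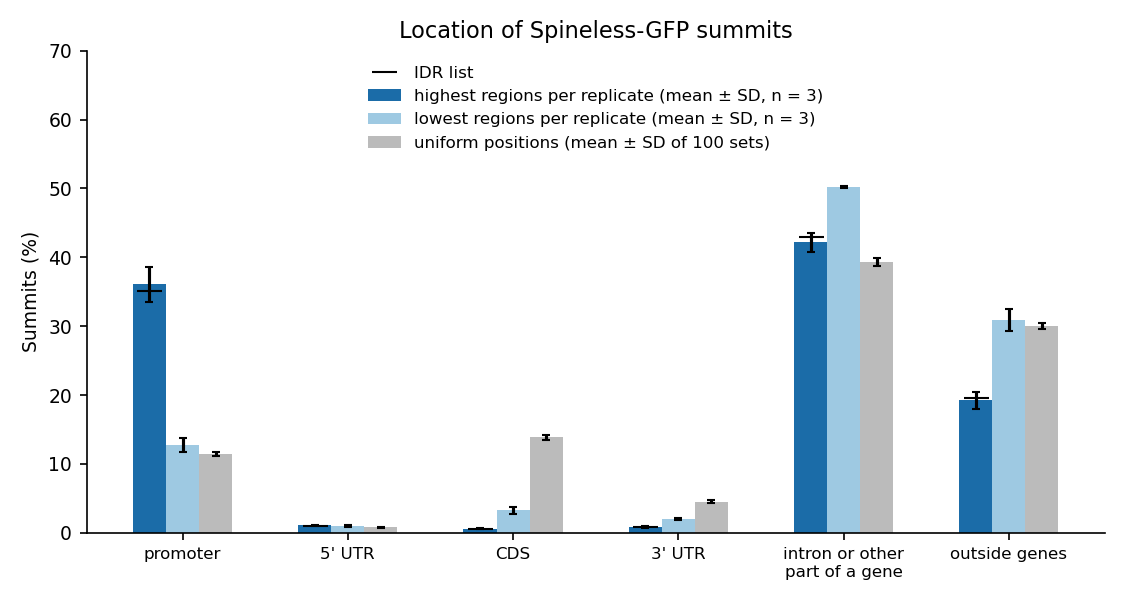
Share of summits (%) in each location class, for the highest and lowest 8942 regions of each replicate (bars, mean ± SD, n = 3), for uniform positions (bars, mean ± SD of 100 sets) and for the IDR list (black lines). Promoters hold 36.1% of the highest regions and 12.8% of the lowest, and coding sequence (CDS) holds few summits in either.

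The 20 highest IDR summits each ranked 48th or better in every replicate list, and 9 of them were at promoters. The highest, with signal 7740, was on 2R at 22569993, within a gene body and 7686 bp from the nearest protein-coding start, that of CG11362. It ranked 2nd, 2nd and 1st in replicates 1, 2 and 3. The promoter summits were at Ugalt (signal 7162, 22 bp from the start, on X at 2703874), larp (6935, 328 bp), CG32772 (6464, 81 bp), yip2 (6402, 181 bp), Cat, which encodes catalase (5927, 309 bp), CG14100 (5778, 89 bp), CG18549 (120 bp), puc, which encodes a phosphatase of the JNK pathway (4057, 11 bp), and Gapdh2 (4047, 164 bp). CG32772 had another summit in its body at 1370 bp. The remaining summits in gene bodies had as nearest start CG11050 at 1024 bp, cbt at 1383 bp, CG9663 at 946 bp and CG13204 at 728 bp, and 1 in a 3' UTR was nearest to dob at 2534 bp. Those outside genes were nearest to CG43389 at 1513 bp, CG4004 at 5029 bp, eEF1gamma at 5728 bp and scyl at 6059 bp. The nearest start need not be the gene that a region acts on.

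Of the 13945 protein-coding genes, 2947 or 21.1% had an IDR summit within 500 bp of a start. Among the 28 gene lists, 8 had more such genes than matched random lists and 3 had fewer. Matching covered the number of starts and gene length, not expression or chromatin access. The counts alone therefore do not show binding specific to Spineless. The appendage, sensory organ, neuronal and zinc finger lists were close to the threshold. Over 20 repeats of the random draws the number with more ranged from 6 to 8, with the appendage list past the threshold in 16 repeats and the zinc finger list in 3. The sensory organ and neuronal calls held in all 20, with adjusted permutation p up to 0.0434 and 0.0498. Exact tail probabilities, added after the data were seen, gave 7 lists with more, without the zinc finger list (exact adjusted p = 0.052), and the same 3 with fewer. Within 250 bp of a start only 3 lists had more, with the 4471 strongest regions 5 did, and by Fisher's exact test against all other genes, without matching, 12 did. The calls for the EGFR, Dpp, Wnt and Hedgehog, ribosomal and chemosensory lists were the 3 that held under all 8 alternatives fixed before the data were examined.

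Cytosolic ribosomal protein genes had the highest share. Of 92 genes, 69 or 75% (95% interval 64.9 to 83.4) carried a promoter summit, where 18.9 were expected (3.65 times, adjusted permutation p = 0.0019 by the matched random lists). The summits sat on the start, at 0 bp for RpS10b (signal 1376) and RpS4 (1343), 47 bp for RpL7 (1214) and 18 bp for RpS27 (1163). RpL36A and RpS13 had none. Heat shock protein genes, second by the ratio to expectation, had 14 of 23 against 5.89 expected (2.38 times, adjusted permutation p = 0.0028). Hsp27 had a summit of signal 2991 at 165 bp, Hsp83, which encodes the fly Hsp90, one of 1905, Hsc70-5 one of 882 and Hsp26 one of 714. The Hsp26 summit had no counterpart within 100 bp in replicates 1 and 2. Hsp60A and Hsp67Ba had none. The heat shock call was lost within 250 bp (adjusted permutation p = 0.0616) and for gene bodies with 5 kb upstream (adjusted permutation p = 0.0672). Proteasome subunit genes, a family taken by symbol prefix without regard to expression, had 6 of 48 against 6.98 expected (adjusted permutation p = 0.907).

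Genes of the signalling pathways of the epidermal growth factor receptor (EGFR), Dpp, Wnt and Hedgehog were also above matched genes, with 31 of 47 against 15.4 expected (2.02 times, adjusted permutation p = 0.0019). Those with the highest promoter signal were the EGFR ligand gene spi (signal 1181), the ETS factor gene pnt (715), aos, which encodes a secreted EGFR inhibitor (709), and the ligand gene Krn (465). Stronger summits farther from a start were not ranked, such as one of signal 2651 nearest to dpp at 5281 bp. The ligand gene vn and sty, which encodes the inhibitor Sprouty, had no promoter summit. Of the Notch signalling genes 13 of 28 carried one against 5.99 expected (2.17 times, adjusted permutation p = 0.0093). They included the Notch target genes E(spl)mdelta-HLH (signal 1812), E(spl)m7-HLH (1502) and E(spl)m3-HLH (1162) and the Notch inhibitor gene numb (1477), while N, which encodes Notch itself, and fng had none. The Notch call was lost within 250 bp of a start (adjusted permutation p = 0.275).

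Genes of the processes in which Spineless is known to act carried promoter summits in part. In the antenna, leg and distal appendage list 21 of 37 genes had a promoter summit against 13.6 expected (1.54 times, adjusted permutation p = 0.0436). They included bowl (signal 1177), the homeobox genes ct (1058) and Dll (755), and aos. The Hox gene Antp and the homeobox gene al had none. The list includes ss itself, counted through a summit 8 bp from its start, where the tagged transgene can add copies of the locus. The test was not repeated without ss. The list shares 6 genes with the EGFR, Dpp, Wnt and Hedgehog list and 6 with the retinal list. The appendage call was lost within 250 bp (adjusted permutation p = 0.17), with the 4471 strongest regions (0.527), with replicate 2 left out (0.213) and with replicate 3 left out (0.273). In the sensory organ and bristle list 16 of 36 had a promoter summit against 9.22 expected (1.73 times, adjusted permutation p = 0.0427). Its strongest promoter summits were at E(spl)mdelta-HLH, E(spl)m7-HLH, numb and the ubiquitin ligase gene neur (845). The proneural genes ac and sc had none. This list shares 11 genes with the Notch list, and its call was lost within 250 bp and 1000 bp (adjusted permutation p = 0.0931 and 0.0655) and with replicate 1 left out (1.87 times, adjusted permutation p = 0.0543). The retinal list, with 20 of 42 against 14.1 expected, did not pass (adjusted permutation p = 0.138), but passed against all other genes by Fisher's exact test (adjusted p = 0.000507). Its highest members by promoter signal were elav, a neuronal RNA-binding protein gene (2100), ttk (758), melt (733) and pnt, and the opsin genes Rh3 and Rh4 had no promoter summit. The bHLH-PAS list had 6 of 11 against 4.40 expected (adjusted permutation p = 0.595, and 0.0285 by Fisher's exact test), with summits at tai (646), trh (562), Met (400), a juvenile hormone receptor gene, and sima (255), and none at sim or tgo. The promoter summit of ss counts in this list and in the Hox list too.

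Ecdysone response genes, which respond to the steroid hormone that drives metamorphosis, had a promoter summit in 26 of 41 cases against 15.9 expected (1.64 times, adjusted permutation p = 0.0056). Eip93F had signal 2033, the cell death gene hid 1924, E23 1775 and the nuclear receptor gene Eip75B 1651. Hr39 and Blimp-1 had none. The call was lost with replicate 3 left out (adjusted permutation p = 0.14), with the 4471 strongest regions (0.133) and for gene bodies with 5 kb upstream (0.0504). The zinc finger list had 13 of 21 against 7.90 expected (1.65 times, adjusted permutation p = 0.0468, and 0.052 by exact probabilities). Its call was also lost within 250 bp (adjusted permutation p = 0.0579), within 1000 bp (0.163), with the 4471 strongest regions (0.133) and for gene bodies with 5 kb upstream (0.132). Its highest members by promoter signal were psq (2236), Cp190 (1711), lola (1402) and Dref (1119), and bab1 and bab2 had no promoter summit.

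The lists with fewer genes carrying a promoter summit were chemosensory receptors, muscle markers and neuronal markers. Of 179 chemosensory receptor genes only Gr77a had a promoter summit (signal 335), where 26.6 were expected (adjusted permutation p = 0.0019), and Ir21a and Gr21a were among those without. Muscle markers had 3 of 22 against 9.19 expected (0.326 times, adjusted permutation p = 0.0176), namely sls (387), Mef2 (380) and Tm1 (254, with no counterpart within 100 bp in replicate 3), while the myosin genes Mhc and Mlc1 had none. Neuronal function markers had 4 of 21 against 9.66 expected (0.414 times, adjusted permutation p = 0.0437), namely elav, jim (736), Syx1A (257) and futsch (210, with no counterpart within 100 bp in replicate 2), and the synaptic genes nSyb and Syt1 had none. Muscle and neuronal calls were lost against all other genes by Fisher's exact test (adjusted p = 0.764 and 1) and with replicate 1 (adjusted permutation p = 0.0901 and 0.0982) or replicate 3 (adjusted permutation p = 0.14 for both) left out, and the neuronal call also without replicate 2 (adjusted permutation p = 0.276). Both were also lost with the 4471 strongest regions (adjusted permutation p = 0.152 for muscle and 0.203 for neuronal), the muscle call within 250 bp (0.133) and the neuronal call for gene bodies with 5 kb upstream (0.0672). No other list passed against matched genes. By Fisher's exact test the dendrite and Polycomb and Trithorax lists had more (adjusted p = 0.000156 and 0.0143) and the Cpr and Tweedle lists fewer (adjusted p = 0.0017 and 0.0111). Hox genes had fewer with replicate 2 or 3 left out (adjusted permutation p = 0.0261 and 0.0483), Cpr genes with the 4471 strongest regions (0.0432) and Tweedle genes for gene bodies with 5 kb upstream (0.028). Their counts against expectation were 16 of 28 against 12.2 for dendrite identity, 7 of 36 against 5.65 for xenobiotic metabolism, 3 of 15 against 5.64 for Hox genes and 12 of 27 against 9.57 for Polycomb and Trithorax genes. Cell cycle genes had 8 of 26 against 7.07 and circadian genes 6 of 13 against 5.22. Glial markers had 4 of 12 against 4.51, fat body markers 3 of 17 against 5.16, hemocyte markers 2 of 15 against 4.72, germline markers 1 of 20 against 4.39 and tracheal markers 3 of 12 against 4.31. Epidermal genes had 3 of 30 against 8.0, Cpr cuticle genes 4 of 70 against 8.92 and Tweedle genes 0 of 25 against 2.53.

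**Figure D2:**
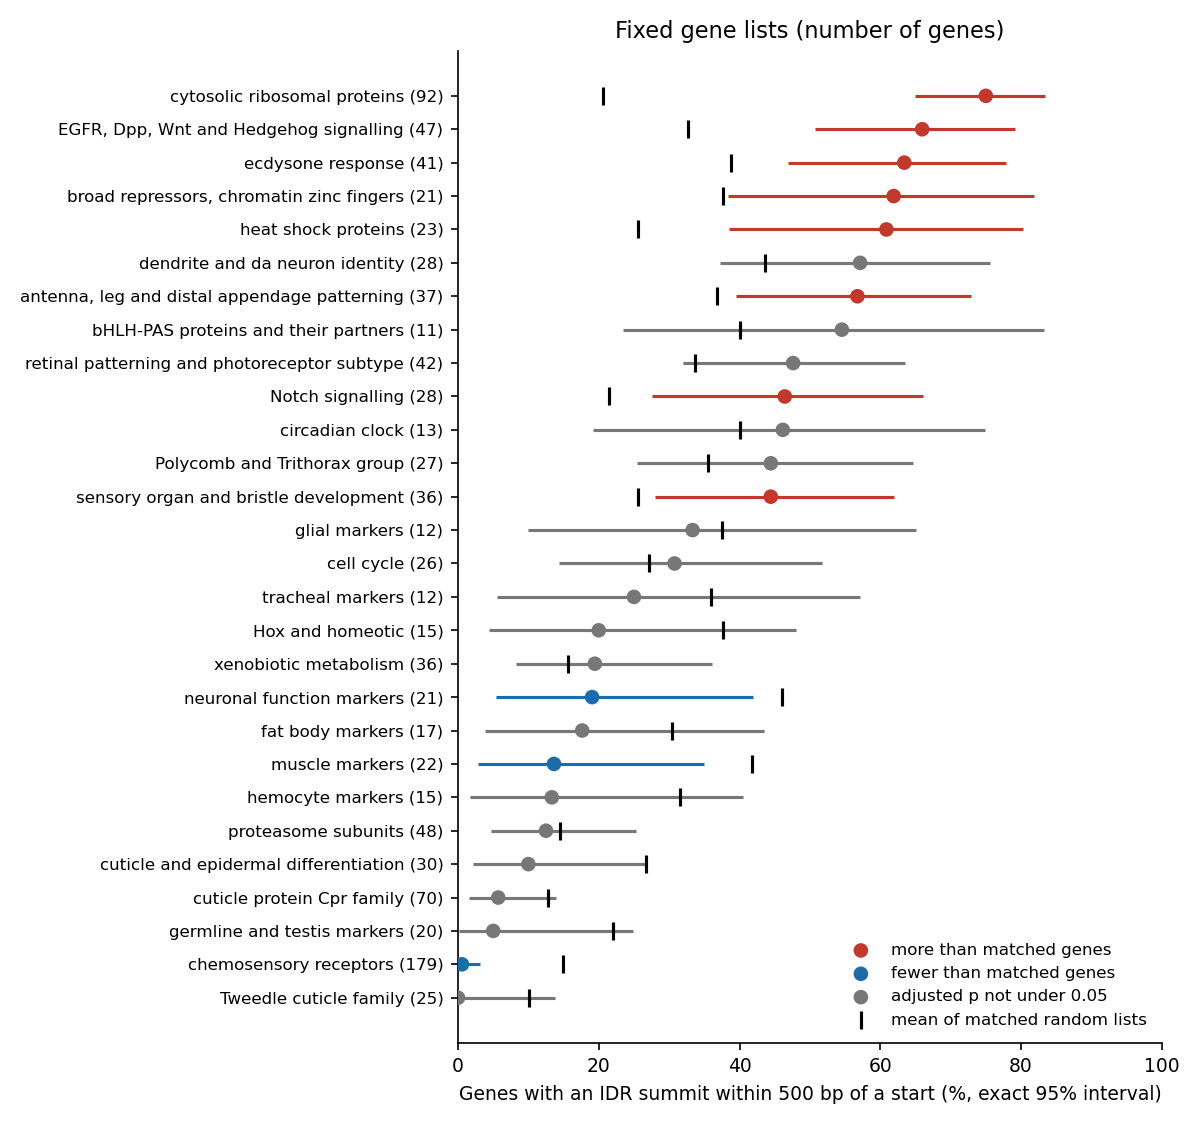
Share of genes (%) of each fixed list with an IDR summit within 500 bp of a start (points, with exact 95% intervals for counting error), coloured by the test against matched random lists, whose mean is the black tick. Ribosomal protein genes stand at 75% and chemosensory receptor genes at 0.559%, and the zinc finger list lies at the threshold.

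The word GCGTG, the core of the element bound by Spineless with its partner Tango, was not more frequent at summits than beside them. It was present within 50 bp of 11.8% of IDR summits and in 13.3% of flanks, a ratio of 0.889 (exact McNemar p = 0.0029, adjusted exact p = 0.00716). In the top lists the ratio was 0.912 ± 0.0545 and in the background lists 1.20 ± 0.0221 (SD, n = 3). It was 0.891 in replicate 1, 0.974 in replicate 2 and 0.871 in replicate 3, with exact McNemar p of 0.00351, 0.513 and 0.00041, so the deficit was not past the threshold in replicate 2. Within 100 bp it was 0.956 (exact McNemar p = 0.0891). The deficit lay in the stronger regions, at 9.77% of summits and 13.8% of flanks for the 4471 strongest (ratio 0.711, exact McNemar p = 4.46e-09), while the lower-ranked 4471 had 13.9% and 12.8% (exact McNemar p = 0.159). The longer TNGCGTG had a ratio of 0.946 (adjusted exact p = 0.627) and ACGTG, the core of other bHLH-PAS dimers, 0.891 (adjusted exact p = 0.042). The E-box CANNTG was at 0.841 (adjusted exact p = 2.36e-19) and CACGTG at 0.802 (adjusted exact p = 0.186). Words above their flanks were TATAAA (1.54, adjusted exact p = 1.46e-27), GAGAGAG (1.48, adjusted exact p = 5.62e-06) and TATCGATA, the DNA replication-related element (2.00, adjusted exact p = 0.00716), though the last rests on 56 and 28 windows. In the background lists GAGAGAG was at 1.38 ± 0.0283 and TATCGATA at 1.68 ± 0.570, each within 1 SD of the top lists (1.501 ± 0.236 and 1.58 ± 0.213), whereas TATAAA was at 0.904 ± 0.0243 against 1.4995 ± 0.0553 (SD, n = 3). The word for Suppressor of Hairless was at 0.585 (adjusted exact p = 0.0201) in the IDR list and at 0.854 ± 0.140 in the replicates' top lists, within 1 SD of the 0.884 ± 0.173 in their background lists (SD, n = 3). Those for AP-1 and Zelda did not pass (adjusted exact p = 0.96 and 0.338), and the ecdysone receptor palindrome was found in 0 windows of either kind.

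**Figure D3:**
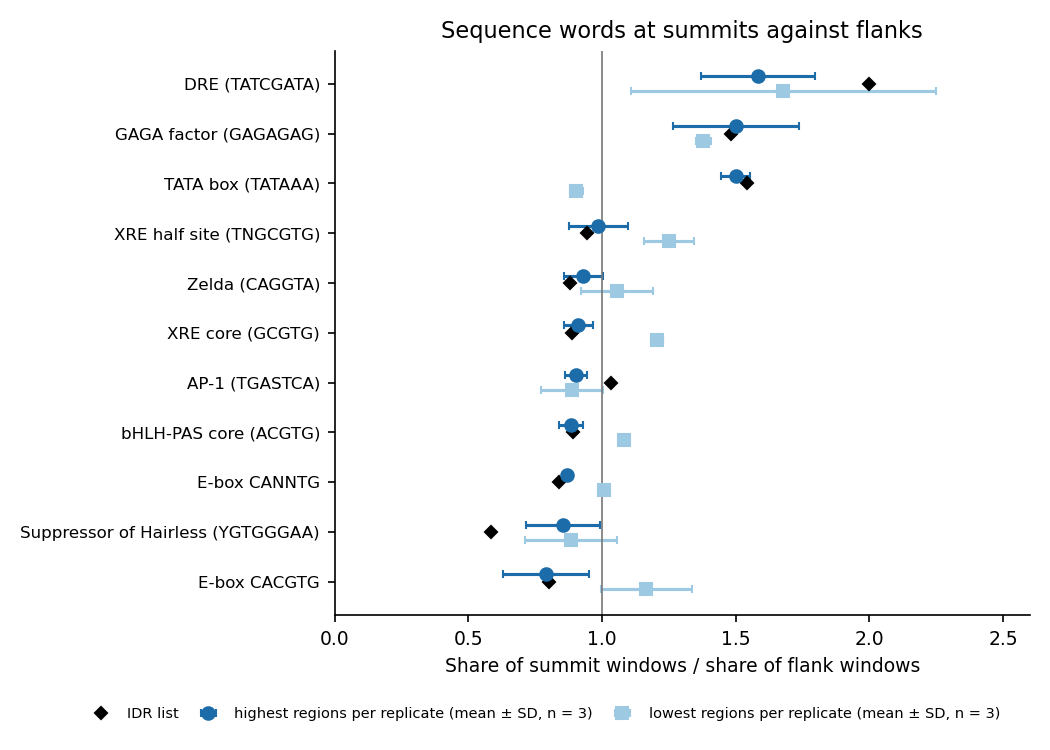
Share of summit windows divided by share of flank windows for 11 words, in the IDR list (diamonds) and in the highest and lowest 8942 regions of each replicate (circles and squares, mean ± SD, n = 3), with 1 marking no difference. GCGTG lies at 0.912 in the highest and 1.20 in the lowest regions, and TATAAA, at 1.54, is among the words above 1.

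Summits were poor in GC. Windows at top-list summits had 38.9% ± 0.376 GC and their flanks 43.2% ± 0.151, while in the background lists the summits had 43.9% ± 0.210 and the flanks 42.0% ± 0.102 (SD, n = 3). The dip was deeper where the signal was higher, with 35.3% at the summits of the 2981 highest IDR regions and 41.2% at those of the 2980 lowest. TATAAA holds no G or C, and like AT content it was above the flanks in the top lists and below them in the background lists. Windows with shuffled bases were compared for GCGTG only. Whether base composition accounts for the ratios of TATAAA, CANNTG or ACGTG was not tested.

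**Figure D4:**
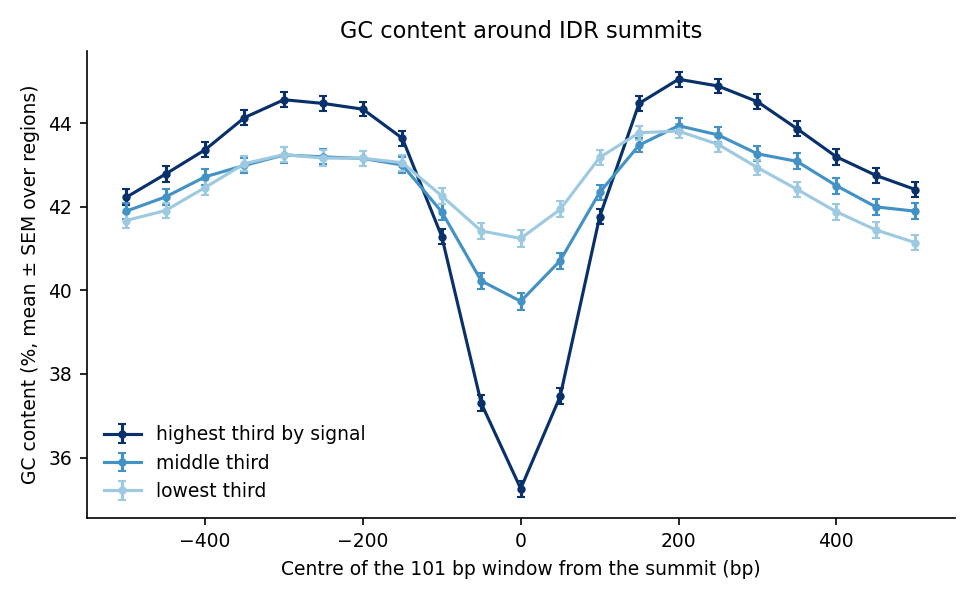
GC content (%, mean ± SEM over regions) of windows reaching 50 bp to each side, centred up to 500 bp from IDR summits, for regions split by signal into the highest 2981, the middle 2981 and the lowest 2980. The highest regions drop to 35.3% at the summit and the lowest to 41.2%.

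The ss gene itself (FBgn0003513, minus strand of 3R, 16374434 to 16403690) carried moderate signal among IDR regions. With 10 kb on each side it held 6 IDR summits. The strongest lay upstream of the gene at 16410108, 6418 bp from the nearest ss start, with signal 362 and rank 3758 in the IDR list, the 58.0th percentile. It ranked 3810, 6206 and 3239 in replicates 1, 2 and 3, and a neighbouring summit lay at 16410307. A summit at 16403698, 8 bp from the start, ranked 6540, and 3 more lay in introns or other parts of ss at 16387244, 16387933 and 16394744. The summit at 16387933 had no counterpart within 100 bp in replicate 2. Among 329 genes within 20% of the length of ss, 69.0% had fewer IDR summits, with a median of 3. The line carries a tagged copy of ss, and reads of that copy and of the resident gene are not separated in these lists. The partner gene tgo (FBgn0264075, 3R, 9016773 to 9020022) had no promoter summit, and the 1 IDR summit within 10 kb, at 9014133 with signal 371, lay at the promoter of Kcmf1.

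**Figure D5:**
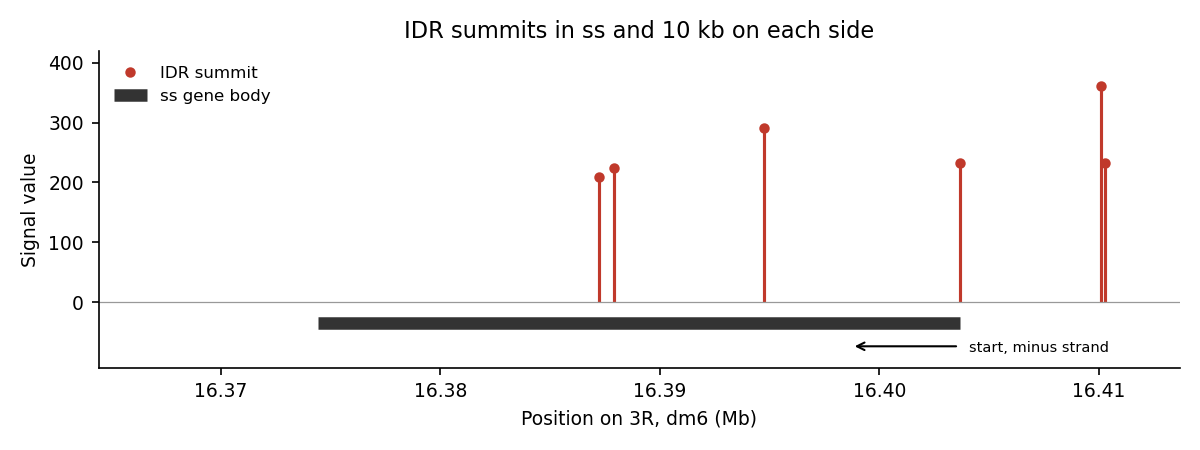
IDR summits (red, height is the authors' signal value) in ss and 10 kb on each side, by position on 3R (Mb, dm6), with the gene body in black and an arrow for the direction of transcription. Of the 6 summits the strongest, of signal 362, lies upstream of the gene.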

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

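The repeats of the random draws and the exact probabilities for gene lists were chosen after the data were seen; the other alternatives were planned. Of the 52 alternatives to the main results 31 kept the call or stayed within the tolerance (counts within 1.5 times, other values within 1 SD of the replicates or the 95% interval). Another 18 moved the value and 3 kept the direction but ended the call. None of the 52 turned a direction. For GCGTG those kept include 2 other measures, the median ratio of the other letter orders (0.744) and real against shuffled summit windows (0.868). The lower-ranked 4471 regions, not among the 52, gave a GCGTG ratio of 1.08 (exact McNemar p = 0.159). The promoter share kept its excess over chance in every alternative. The share of IDR regions in the top list of every replicate was 33.0% with the list size halved and 82.9% with it doubled, 44.5% within 50 bp, 70.8% within 250 bp, 71.9% by overlap, 89.5% for the 4471 strongest regions and 65.9% to 69.1% with 1 replicate left out, which by construction asks for agreement of fewer lists. The rank correlation became 0.815 as Pearson's r of log2 signal and 0.723 to 0.801 with 1 replicate left out. The number of gene lists above matched genes was 3 within 250 bp, 5 for the strongest 4471 regions and 5 for gene bodies with 5 kb upstream; the cause was not tested. It was 12 by Fisher's exact test, which does not match on starts and length, at the edge of the tolerance. The GCGTG ratio was 0.956 within 100 bp and 0.881 to 0.932 as the mean of the top lists of the other replicates with 1 left out, which adds no test to those of the single replicates. It was 0.711 for the strongest 4471 regions and 0.772 for summits over 500 bp from a start. The ss percentile was 87.5 in the pooled list and 88.0 to 88.9 in the replicate lists with 1 left out, since those lists are longer. Over the 28 gene lists with 8 alternatives each, 186 outcomes kept the call or its absence, 28 lost a call and 10 gained one. Read depth is unknown, so what it limits was not assessed.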

Other observations

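The tests of letter orders and of the weaker regions for GCGTG, and of neighbours and other protein families for ribosomal genes, were chosen after the pattern was seen, as was the word CACTGAGA. The test on shuffled windows was added after the letter orders had been seen. No biological explanation was tested for any pattern, because the design holds one group, and no expression data or flies without the tag were analysed here.

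Promoter summits were somewhat more common among the strongest regions, at 39.2% of the highest 1789 (95% interval 37.0 to 41.5) against 32.1% of the lowest 1789 (29.9 to 34.3). Summits were rare in annotated transposable elements, with 15 of 8942, or 0.168%, against 5.75% of uniform positions. The uniform positions covered whole arms, whether or not regions could be called there. No share is given for the background lists, so avoidance of these elements is not shown. Genes of mitochondrial ribosomal proteins, a set chosen after the data were seen, had promoter summits in 15 of 73 cases against 7.36 expected from matched random lists (two-sided permutation p = 0.0094).

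GCGTG was not enriched at summits, and low GC content is a candidate explanation. In copies of the same windows shuffled with their dinucleotides kept, the ratio of summits to flanks was 0.874. The measured ratio divided by it was 1.02 (95% bootstrap interval 0.939 to 1.09), consistent with base composition accounting for the ratio. It does not account for the level: real windows held GCGTG less often than the mean of 10 shuffled copies, at 11.8% against 13.4% of summits and 13.3% against 15.4% of flanks. A separate single shuffled copy of the summit windows gave a ratio of real to shuffled of 0.868 (exact McNemar p = 6.55e-05). The other 19 orders of the letters all had ratios below 1, with a median of 0.744 and a highest of 0.979. Words of the same composition were thus also less frequent at summits. Of these orders 18, or 94.7%, had a lower ratio than GCGTG. At 0.889 it lay above their 95th percentile of 0.855, the outcome that was to count against low GC content. That outcome shows a smaller deficit of GCGTG than of most such words. It cannot speak against low GC content as a source of the missing excess. Of these orders 8 lack the CG dinucleotide that GCGTG holds, which cannot alone explain 18 lower ratios. The shuffled windows gave nearly the measured ratio and most letter orders a lower one. Whether base composition alone sets the ratio stays undecided. An enrichment in weaker regions hidden by the strongest ones stays open: the lower-ranked IDR regions gave 1.08, in that direction but short of the threshold (exact McNemar p = 0.159).

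Ribosomal protein genes carried summits more often than matched genes. Starts shared with neighbours do not account for it: the 21 genes with no other start within 1000 bp gave 11 with a summit against 3.34 expected, 3.30 times (two-sided permutation p = 0.0002, the smallest the draws can give). Mitochondrial ribosomal genes, at 20.5% with an upper 95% bound of 31.6%, argue against equal recovery of all widely expressed genes. That bound lies below the lower bound of 64.9% for ribosomal genes. Proteasome genes were at 12.5%, but that list was taken by symbol prefix, and any members that are not widely expressed could lower its share. Expression was not examined for either set. Very high transcription or chromatin access, which may raise recovery with any antibody, stays open and was not tested.

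A word outside the planned set, CACTGAGA, was present within 100 bp of 257 IDR summits and in 53 flank windows, a ratio of 4.85 (exact McNemar p = 2.77e-33), and of 5.34, 5.06 and 5.06 in the top lists of replicates 1, 2 and 3. Ranked among all words of 8 bases with at least 2 G or C in the 4471 odd-ranked regions it came first, and in the 4471 even-ranked regions it was found at 122 summits and 27 flanks (adjusted exact p = 1.27e-14 over 10 words); it had been noticed over all regions before, so the split is not an independent discovery. Of the 257 summits 0% lay in an annotated transposable element. Only 15 of all 8942 IDR summits did, so most of the 257 could not have. The test therefore cannot decide whether sequence derived from such elements plays a part. Repeats remain a candidate explanation: 60.5% of the 271 copies of CACTGAGA at summits lay in sequence masked as repeats, compared with 21.9% of all bases within 100 bp of IDR summits. The classes of masked repeat were not separated. Only 15.2% of these summits were at promoters, against 35.7% of the others.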
